A study of Homo sapiens with 4 samples.

How the data were processed

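RNA of HCT-15 and LoVo colorectal cancer cells treated for 48 h with 100 µg/ml of anti-FGFR2IIIc or anti-GFP antibody was labelled with the dye Cy3 and hybridised to 1-colour Agilent human oligonucleotide microarrays, per the labels. The 4 arrays were taken as 4 groups of 1, by the cell line and the treatment stated in the labels. All 4 arrays lay on 1 slide, per the file headers, so line and antibody were not split between slides, although each group kept its own position on it.

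The deposited scanner files hold the spot intensity as the authors' scanner software made it. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background, corrected spatial trends within each array and put a substitute value where a signal was not above background. The labels name version 9.1 of the same software instead. No normalization between arrays had been applied to these intensities. The other columns used were the software's own error of each processed intensity, the raw mean and local background intensities, and the deposited spot flags, a unit of their own (other) per the file headers. The deposited series table holds a linear signal. In its HCT-15 columns the authors had divided the signal of each spot by the array's 75th percentile, as found from the values (slope 1 and r = 1 against the scanner files on the log2 scale). The LoVo columns of the authors' deposited table hold 64 values of another kind (other), and these were used only to describe that table.

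Each array had 45015 spots, of which 43376 were not controls, and these held 41000 probes. Between 61 and 78 outlier spots per array were left out, and 0 spots were saturated. The log2 of the processed intensity was taken with no pseudocount, the array's 75th percentile was subtracted, and the spots of a probe were averaged. Replicate spots of a probe on 1 array had a median SD between 0.046 and 0.063 on the log2 scale. Probes were named from a gene table of assembly GRCh38.p14, with 26457 matched by transcript accession, 1464 by symbol and 425 by an older symbol, while 12654 kept the name in the file. The result was 30811 genes or transcripts, 18453 of them matched to that table of genes. For the 7278 matched genes with more than 1 probe, the probe with the highest mean over the 4 arrays was used. Probe coordinates are on hg19 as the file gives them. Placing in exons or untranslated regions was not analysed here, and among named genes 7 probes were placed by the file on another chromosome than the gene.

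Within a line, each gene well above background on both arrays was given its log2 ratio of anti-FGFR2IIIc over anti-GFP, with an error from the scanner software's signal errors, whose error model carries a multiplicative term of 0.1. Genes at 2-fold or more were counted without a test. A gene above background on 1 array of the pair was given a bound, the lowest fold that its signal allows over the lowest signal well above background. For both lines together, a linear model with terms for line and antibody was fitted in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8) to 20462 genes well above background on at least 2 arrays, with 1 residual degree of freedom and 2.75 prior degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. For the antibody the cell line is the unit of replication (n = 2 lines). The number of arrays limits the precision of every value.

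Before the data were examined, 45 gene lists of pathways and cell type markers were fixed, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 fitted genes, 42 in number, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. At the preset correlation the p-value compares the genes of a list with the other genes and does not measure a spread between cultures. With an estimated correlation camera rests on the 1 residual degree of freedom and could hardly call any list. Within each line, the median of a list was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. The named genes were the FGF receptors, the genes 2-fold or more in both lines (up to 12 each way in the same direction, 6 in opposite directions), and the 6 highest and 6 lowest in each line. Also named were up to 4 genes per list with the largest absolute value of the mean log2 ratio over the 2 lines. For the difference between the lines they were the 10 highest, the 10 lowest and 6 bounds each way. Transcripts with clone or placeholder names were counted and not named, and XIST and Y-linked genes were left out of naming. Some genes that the rule names are not reported here.

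The alternatives were normexp background correction with an offset of 50, quantile and median normalization, the deposited table, the mean of a gene's probes, other filters and fold thresholds, a pseudocount, an intensity trend in the variance prior, a fit without the second term, other list tests, and leaving out single arrays. A loess trend on probe GC content and signal was removed as an alternative chosen after seeing the data. The fit was tested on simulated data with 20462 genes. Of 50 genes changed by each log2 of 1, 2, 3 and 4 in both lines, 18%, 90%, 96% and 98% were called for the antibody, with 5 false calls among 20262 unchanged genes. All these genes were changed at once and by the same amount in both lines. That makes the adjusted p threshold easier to reach than where few genes change. The shares for the antibody therefore do not carry over to the real arrays. For the line difference the shares were 14%, 96%, 100% and 98%, with 9 false calls. All 3 lists shifted by 0.5 were called and 0 of 32 unshifted ones, and 2 of 62 unshifted list values lay outside the central 95% of random lists. The simulated genes varied independently of one another, so these list results do not show how often lists of correlated genes are called falsely. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the files were read with pandas 2.3.3.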

Results

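Transcript levels were measured in HCT-15 and LoVo, established human colorectal cancer cell lines, after 48 h with 100 µg/ml of a monoclonal antibody against human FGFR2IIIc. Control cells of each line received the same amount of an antibody against GFP, the green fluorescent protein of jellyfish, which human cells do not make. FGFR2IIIc is a splice form of fibroblast growth factor receptor 2, a cell surface tyrosine kinase that binds fibroblast growth factors, and the title of the series states that expression signatures under this antibody were sought. Each of the 4 combinations of line and antibody had 1 array, so the antibody difference within a line had no replicate check and carries no p-value. Over both lines the antibody comparison rested on 2 lines, and the comparison between the lines on 2 arrays per line. Of the 43376 non-control spots on an array, 66.7% were well above background in HCT-15 with anti-GFP and 66.9% with anti-FGFR2IIIc, against 64.5% and 67.7% in LoVo. The 75th percentile of the signal was 926, 880, 833 and 968 intensity units on these arrays in the same order. Values are log2 ratios of anti-FGFR2IIIc over anti-GFP, and the error beside each, written after ±, is the scanner software's signal error carried through to the ratio.

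Transcripts of the targeted receptor and of its relatives differed from the control by less than 2 times the scanner error in both lines. FGFR2 had a log2 ratio of -0.27 ± 0.22 in HCT-15 and -0.17 ± 0.21 in LoVo. Its probe lies on chromosome 10 from 123238271 to 123238331 (hg19, per the file), and whether it separates the IIIc splice form from others was not determined here. FGFR1 had ratios of 0.00 ± 0.21 and -0.16 ± 0.20, FGFR3 of -0.08 ± 0.21 and -0.11 ± 0.20, and FGFR4 of 0.30 ± 0.23 and -0.10 ± 0.21 in HCT-15 and LoVo. FGFRL1, a receptor relative that lacks the kinase domain, had ratios of -0.05 ± 0.20 and -0.16 ± 0.20. Among receptor partners, the adaptor FRS2 had ratios of 0.35 ± 0.21 and 0.14 ± 0.22, and the docking protein GAB1 of -0.74 ± 0.31 and -0.21 ± 0.34. The list of FGF receptors and partners had a median log2 ratio of 0.01 over 14 measured genes in HCT-15 and of -0.07 over 13 in LoVo. Genes that the ERK kinase pathway downstream of such receptors switches on had medians of 0.03 (17 genes) and -0.01 (18 genes). Within that list the phosphatase gene DUSP6 had ratios of -0.22 ± 0.20 and -0.52 ± 0.20, and DUSP5 of 0.17 ± 0.21 and 0.76 ± 0.20. The list medians ranked at the 59.2 and 53.4 percentiles of random lists of equal size and expression, and no antibody difference of these genes passed the test over both lines described with the joint fit.

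In HCT-15, the highest measured gene under anti-FGFR2IIIc was CXCL1, which encodes a chemokine that attracts neutrophils and was 10.8-fold higher (log2 3.43 ± 0.25). The gene LCN2, which encodes a secreted iron-binding protein of the innate defence, was 9.13-fold higher (3.19 ± 0.21). Beside them stood GPR149, an orphan receptor gene (3.20 ± 0.35), the phosphatase gene PTP4A3 (2.98 ± 0.33), ATL1, which encodes a GTPase that shapes the endoplasmic reticulum (2.79 ± 0.24), and the non-coding SPANXA2-OT1 (2.73 ± 0.29). The lowest named genes were GNMT, a glycine methyltransferase gene (-2.68 ± 0.26), the semaphorin gene SEMA3F (-2.54 ± 0.33), RIN2 (-1.75 ± 0.29), TRIM38 (-1.50 ± 0.23), the transcription factor gene FOXC2 (-1.49 ± 0.21) and SYDE1 (-1.42 ± 0.32). In all, 55 genes were higher and 50 lower by 2-fold or more among 19370 well above background on both arrays, which is 0.542%. The scanner error alone would put 9.27 genes past 2-fold. A further 115 genes were above background with anti-FGFR2IIIc alone and 131 with anti-GFP alone, with a bound of 2-fold or more. Of the 105 genes, 95.2% lay in the dimmer part of the measured genes, below the median signal, and only 8 had another measured probe. That probe pointed the same way for 7 and reached 2-fold for 1; for SEMA3F it gave -0.06 and for TRIM38 -0.37.

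In LoVo the highest measured gene was LTB. It encodes lymphotoxin beta, a membrane cytokine of the tumour necrosis factor family, and was 31.5-fold higher (log2 4.98 ± 0.24). The neutrophil chemokine gene CXCL8 was 9.61-fold higher (3.26 ± 0.24), PI3, which encodes the protease inhibitor elafin, 8.42-fold (3.07 ± 0.21), and CXCL1 7.04-fold (2.82 ± 0.20). ADGRE1, an adhesion receptor gene, had a ratio of 2.62 ± 0.33, and BIRC3, an inhibitor of apoptosis that also acts in NF-kB signalling, of 2.54 ± 0.21. The lowest named genes were TDRKH (-2.82 ± 0.22), ANKRD20A11P (-2.40 ± 0.25), the peptide transporter gene SLC15A3 (-2.39 ± 0.29), PRM1 (-2.06 ± 0.33), the interferon-induced MX2 (-1.95 ± 0.36) and USP32P2 (-1.76 ± 0.24). Altogether 55 genes were higher and 60 lower by 2-fold or more among 18835 measured, or 0.611%, where the scanner error alone would give 7.61. Bounds of 2-fold or more were met by 80 genes above background with anti-FGFR2IIIc alone and by 152 with anti-GFP alone. Of the 115 genes, 87.8% lay below the median signal; 12 had another measured probe, which pointed the same way for 11 and reached 2-fold for 3. The other probe of TDRKH gave -0.05 and that of ANKRD20A11P -0.55.

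Across both lines, 5 genes were 2-fold or more higher under anti-FGFR2IIIc. They were CXCL1, LTB (4.16-fold in HCT-15, log2 2.06 ± 0.20), the neutrophil chemokine gene CXCL2 (3.66-fold, 1.87 ± 0.27, and 5.21-fold, 2.38 ± 0.20, in HCT-15 and LoVo), the calcium-binding S100A3 (1.72 ± 0.26 and 2.47 ± 0.23) and the long non-coding UCA1 (1.57 ± 0.20 and 1.89 ± 0.21). The probes of CXCL1 and CXCL2 lie on chromosome 4 from 74736850 to 74736909 and from 74964342 to 74964401 (hg19), those of LTB on chromosome 6 from 31548469 to 31548528, of S100A3 on chromosome 1 from 153519998 to 153520057, and of UCA1 on chromosome 19 from 15946035 to 15946092. CXCL8 and LCN2 were dim on 1 array each: CXCL8 was at least 2.61-fold higher in HCT-15 and LCN2 at least 3.02-fold higher in LoVo. Independent lists of 41 higher genes in HCT-15 and 40 in LoVo, among 17956 genes above background on all 4 arrays, would share 0.0913 genes. Lower in both lines by 2-fold or more was 1 transcript without a gene symbol, against 0.0922 expected for lists of 36 and 46. There were 3 genes higher in HCT-15 and lower in LoVo, of which USP32P2 (1.07 ± 0.21 and -1.76 ± 0.24) has a symbol, and 0 with the opposite arrangement. The lists behind these 3, of 41 and 46 genes, are of like size to those above, so opposite genes also exceed what independent lists would share. An excess over independent lists is therefore not by itself a sign of a shared response. Across all 17956 genes the ratios of the lines were nearly unrelated, with a Pearson r of 0.102 and a Spearman rho of 0.038, and r was 0.066 without the NF-kB list. Genes are not independent replicates, so these coefficients carry no p-value.

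**Figure D1:**
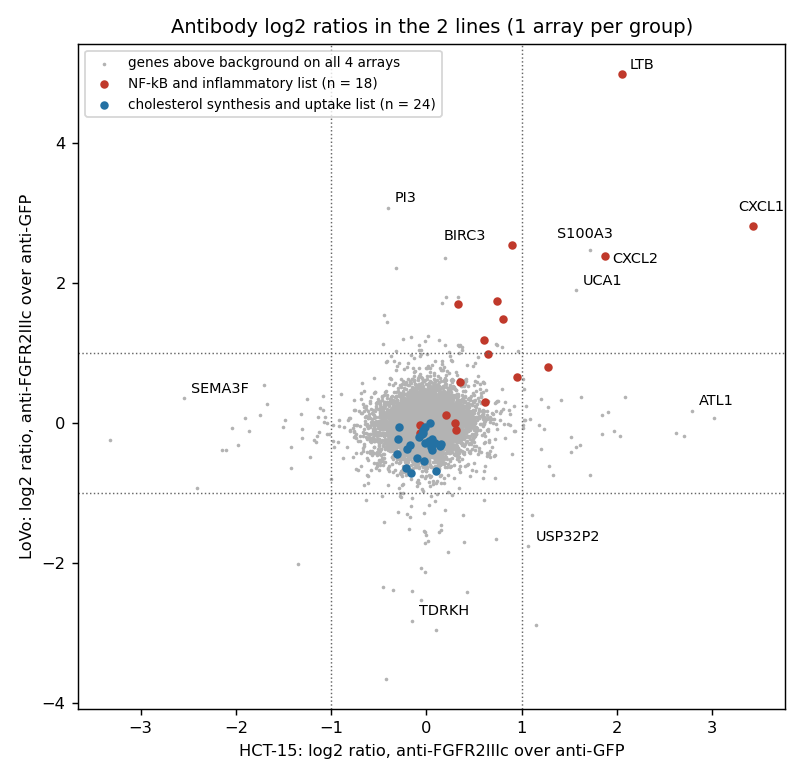
Log2 ratio of anti-FGFR2IIIc over anti-GFP in LoVo (vertical axis) against HCT-15 (horizontal axis) for genes above background on all 4 arrays, 1 array per group, with dotted lines at 2-fold. Genes of the NF-kB and inflammatory list (red) reach the upper right, where CXCL1 stands at 3.43 and 2.82 and LTB at 2.06 and 4.98, while 0 of the 24 genes of the cholesterol list (blue) lie above 0 in LoVo.

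The NF-kB and inflammatory list was higher under anti-FGFR2IIIc in both lines. Its genes are targets and regulators of NF-kB, the transcription factor that drives the response to tumour necrosis factor and bacterial products. In HCT-15, 16 of 18 measured genes were above 0, 4 of them by 2-fold or more, with a median log2 ratio of 0.63. In LoVo, 18 of 21 were above 0, 9 by 2-fold or more, with a median of 0.80. NFKBIA, which encodes an inhibitor of NF-kB, stood at 0.75 in HCT-15 and 1.74 in LoVo, and TNFAIP3, another inhibitor of the pathway, at 0.61 and 1.19. The genes of NF-kB subunits in the list stood at 0.81 and 1.48 (RELB), 0.64 and 0.99 (NFKB2) and 0.35 and 0.59 (NFKB1). Cytokine genes of the list that were dim in the controls gave bounds: CCL20 was at least 15.6-fold higher in LoVo, and TNF at least 2.17-fold in HCT-15 and 1.99-fold in LoVo. Each of these 7 genes was chosen after its values were seen. Over both lines the list was higher by camera, limma's gene list test (adjusted p = 3.33e-18, 42 lists tested, 22 genes, median 0.86, mean 1.12). That p-value compares the list's genes with the other genes on these arrays and does not measure a spread between cultures. With an estimated correlation between its genes that call was lost (adjusted p = 0.928 with an estimated correlation), and fry, limma's test of a list on its own, gave an adjusted p of 0.632. Adjusted over the list alone, 14 of the 22 genes passed and all 14 were higher, against 0 adjusted over all genes. Of these 14, CXCL8 and TNF had arrays not above background, so their fitted values rest on substitute signals.

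**Figure D2:**
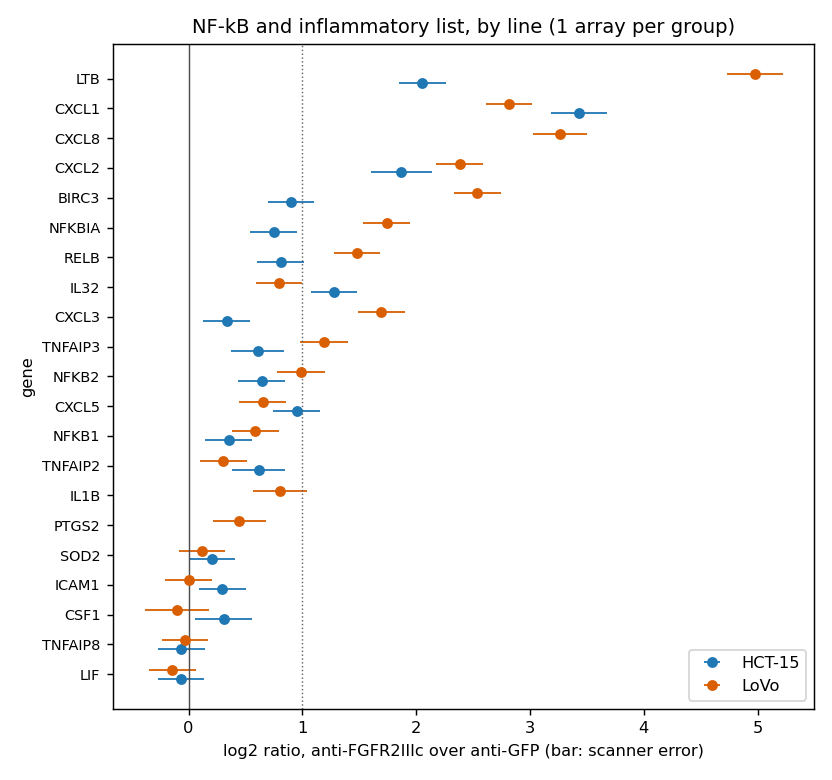
Log2 ratio of anti-FGFR2IIIc over anti-GFP for each gene of the NF-kB and inflammatory list measured in a line (1 array per group), with bars for the scanner error. Of the measured genes, 16 of 18 in HCT-15 and 18 of 21 in LoVo lie above 0, up to 3.43 for CXCL1 in HCT-15 and 4.98 for LTB in LoVo.

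No single gene passed the joint test of the antibody over both lines. The smallest adjusted p, 0.232, belonged to CXCL8, but it rests on a substitute value, since the HCT-15 control signal was not above background and the ratio there is only a bound. Among genes above background on all 4 arrays, CXCL1 came nearest (adjusted p = 0.369, log2 3.12 ± 0.18 SE). UCA1 (adjusted p = 0.586) and CXCL2 (adjusted p = 0.632) were higher in both of the 2 lines. By limma, 0 of 20462 genes passed an adjusted p of 0.05, and 954 had an unadjusted p under 0.05, where chance alone gives 1023. The count depended on the settings of the fit. It was 33 (23 higher, 10 lower) with an intensity trend in the variance prior, 149 (57 higher, 92 lower) with normexp background correction, and 4, all higher, when the genes were those above background on all 4 arrays: CXCL1 (adjusted p = 0.0040), CXCL2 (0.0105), UCA1 (0.0105) and S100A3 (0.0337). All 4 were among the 33 and among the 149, and 32 of the 33 were among the 149.

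The lists of lipid synthesis genes were lower under anti-FGFR2IIIc. Of 24 genes for cholesterol synthesis and uptake, 0 were above 0 in LoVo (median -0.29, percentile 0 of matched random lists) and 9 in HCT-15 (median -0.03, percentile 0.09). The sterol sensor gene INSIG1 had ratios of -0.22 ± 0.20 and -0.64 ± 0.20, TM7SF2, a sterol reductase gene, of -0.16 ± 0.20 and -0.71 ± 0.20, and HMGCS1, an early enzyme of the pathway, of -0.30 ± 0.20 and -0.44 ± 0.20 in HCT-15 and LoVo. Over both lines the list was lower by camera (adjusted p = 4.15e-06, median -0.15). It did not pass with an estimated correlation (adjusted p = 0.928 with an estimated correlation), a version that could hardly call any list. Fatty acid synthesis genes had 0 of 11 above 0 in LoVo (median -0.26, percentile 0) and 3 of 10 in HCT-15 (median -0.03, percentile 6.55), with the elongase gene ELOVL6 at -0.90 ± 0.21 and the desaturase gene SCD at -0.34 ± 0.20 in LoVo. That list was lower over both lines (adjusted p = 0.0197, median -0.11; adjusted p = 0.928 with an estimated correlation).

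Mitotic genes were slightly higher in LoVo. Of 30 genes for G2/M and mitosis, 29 were above 0 in LoVo (median 0.17, percentile 100). In HCT-15 18 were above 0 (median 0.01), and against matched random lists this median was on the low side, at percentile 4.93. The mitotic kinase gene AURKA stood at 0.17 ± 0.20 in HCT-15 and 0.36 ± 0.20 in LoVo and the centromeric histone gene CENPA at 0.13 ± 0.20 and 0.38 ± 0.20. Camera called the list higher over both lines (adjusted p = 0.00568, median 0.10; adjusted p = 0.928 with an estimated correlation). Genes regulated by the PI3K-AKT-FOXO pathway of growth factor signalling were lower by camera (adjusted p = 0.0271, median -0.09; adjusted p = 0.928 with an estimated correlation). That list was not divided by whether the pathway raises or lowers a gene. Its lower values therefore do not tell whether the pathway was more or less active. In the list 3 of 16 genes were above 0 in HCT-15 (percentile 0.34) and 6 of 16 in LoVo (percentile 27.6). PDK4, which restrains pyruvate use, stood at -0.76 ± 0.32 and -0.13 ± 0.25, CCNG2 at -0.40 ± 0.21 and -0.34 ± 0.20, and TRIB3 at -0.05 ± 0.20 and -0.76 ± 0.20. The other 37 lists did not pass, and the nearest were heat shock proteins and ribosome biogenesis (adjusted p = 0.0512 each). Adjusted over the list alone, 7 other lists had 1 gene past the threshold, chosen after its values were seen: AKR1B10, CXCL8, CLDN5, AGR2 and, in 3 lists, CCN2. AKR1B10 and CXCL8 were higher, and CLDN5, AGR2 and CCN2 lower. The lists that hold CCN2 are those of TGF-beta and BMP targets, YAP-TEAD targets and immediate early genes. Of these genes, AKR1B10, CXCL8 and CCN2 were not above background on all 4 arrays.

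Within single lines, several lists stood at the ends of the random lists without moving together in both. Genes induced by TGF-beta and BMP had a median of -0.14 in HCT-15 (4 of 14 above 0, percentile 0.03) and of 0.17 in LoVo (14 of 16 above 0, percentile 100). The BMP targets ID1 and ID3 were at 1.11 ± 0.20 and 1.03 ± 0.20 in LoVo, and at -0.08 ± 0.20 and -0.32 ± 0.20 in HCT-15. Interferon response genes had a LoVo median of 0.24 (20 of 27 above 0, percentile 100) and an HCT-15 median of 0.02 (percentile 48.5). Among them RIGI, a sensor of viral RNA, was at 0.59 ± 0.21 and OAS3 at 0.50 ± 0.20 in LoVo. YAP-TEAD target genes had a LoVo median of 0.18 (15 of 19 above 0, percentile 100) and an HCT-15 median of -0.01 (percentile 13.7). Epithelial adhesion genes had 5 of 25 above 0 in HCT-15 (median -0.12, percentile 0) and 18 of 26 in LoVo (median 0.06, percentile 98.5). The tight junction gene CLDN2 was nonetheless below 0 in both, at -0.57 ± 0.20 and -0.46 ± 0.20. Ribosomal protein genes had 50 of 52 above 0 in HCT-15 (median 0.13, percentile 99.8) and 2 of 52 in LoVo (median -0.12, percentile 0.07). With a trend of the ratio on probe GC content and signal removed, an alternative chosen after seeing the data, these medians were 0.01 (percentile 84.2) and -0.02 (percentile 8.26), no longer at the ends. Epithelial adhesion then had an HCT-15 median of -0.15 (percentile 0) and a LoVo median of 0.05 (percentile 93.6). Heat shock protein genes were above the random lists in both lines (17 of 18 above 0, median 0.13, percentile 99.0, and 11 of 16, median 0.09, percentile 99.9). Leukocyte markers, which cultured epithelial cells should lack, had medians of 0.02 (7 genes) and -0.11 (6 genes). In all, 29 of 82 list values lay outside the central 95% of random lists, where lists of unrelated genes would give 4.1. These percentiles describe 1 pair of arrays each and are not a test of the antibody.

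**Figure D3:**
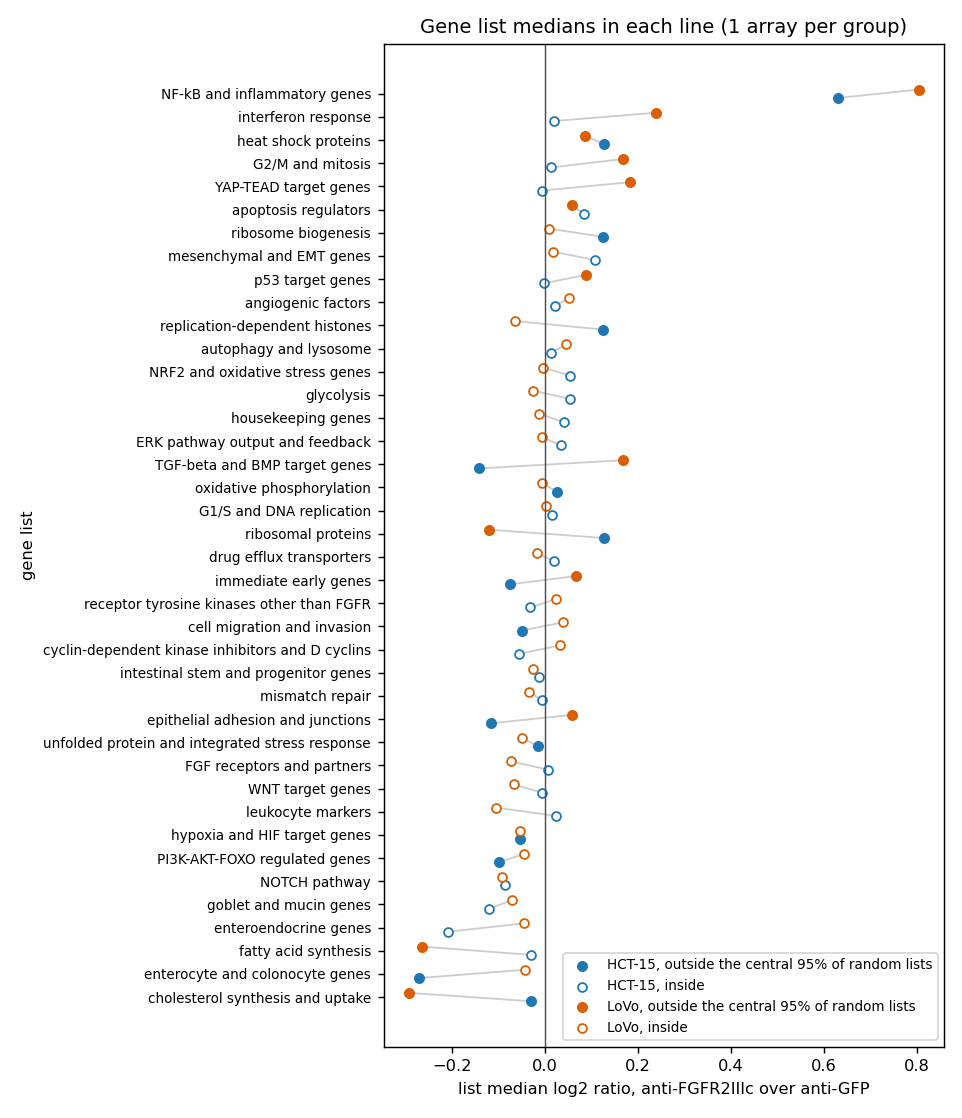
Median log2 ratio of anti-FGFR2IIIc over anti-GFP of each gene list that had a median in both HCT-15 and LoVo (1 array per group), with filled symbols for medians outside the central 95% of random lists of equal size and expression. The NF-kB and inflammatory list stands apart at 0.63 and 0.80, and the cholesterol list has the lowest LoVo median plotted, -0.29.

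The lines themselves differed far more than the antibodies did. Among genes above background on all 4 arrays, LoVo was higher in S100P, a calcium-binding protein gene (log2 11.28 ± 0.11 SE, adjusted p = 1.68e-04), in GPX2, a glutathione peroxidase gene of the gut (8.14), in FST, which encodes the activin inhibitor follistatin (7.79), and in the goblet cell gene SPINK4 (7.43). HBA2 (7.85), DNAJA4 (7.67), RPP25 (7.63), TCF4 (7.58), NEURL1 (7.24) and UGT1A6 (7.18) completed the highest 10 of these genes. Among the same genes HCT-15 was higher in the small heat shock protein gene HSPB1 (log2 LoVo over HCT-15 of -7.13, adjusted p = 1.90e-04), the glutathione transferase gene GSTM3 (-6.58), IGFBP2, which binds insulin-like growth factors (-6.19), and the retinoic acid binding protein gene CRABP2 (-5.69). TCEAL8 (-6.69), MYADM (-6.31), ARHGAP23 (-6.28), FRAS1 (-6.10), ADGRG1 (-5.56) and TNNC1 (-5.20) were the rest of the lowest 10 of these genes. The HSPB1 probe used is placed on chromosome 9 by the file, and the other probes, on chromosome 7 where the gene lies, gave -7.18 and -7.37. Genes not above background in 1 line gave bounds, several of them larger than the folds above. The carcinoembryonic antigen relative CEACAM6 was at least 3309-fold higher in LoVo, the protease inhibitor gene SPINK6 at least 4228-fold and the mucin glycosyltransferase gene GCNT3 at least 3493-fold. The non-coding AFAP1-AS1 was at least 919-fold higher in HCT-15, and QPRT, an enzyme of NAD synthesis, at least 865-fold.

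By limma, 10883 of 20462 genes (53.2%) differed between the lines at an adjusted p under 0.05, with 5075 higher in LoVo and 5808 higher in HCT-15. Of these, 1179 were 4-fold or more higher in LoVo and 722 in HCT-15, and 659 genes were above background in LoVo only and 699 in HCT-15 only. The FGF receptors were among them: FGFR3 (log2 3.71 ± 0.09 SE, adjusted p = 2.61e-04), FGFR4 (1.92 ± 0.14), FGFR2 (1.26 ± 0.10, adjusted p = 0.00241) and FGFR1 (0.70 ± 0.10) were higher in LoVo, and FGFRL1 (-1.99 ± 0.10, adjusted p = 8.73e-04) in HCT-15. The control arrays of the lines correlated with r = 0.944 across genes, and the arrays within a line with r = 0.997. Without a filter on dim probes the count for the difference between the lines was 5186. The arrays of a line carried different antibodies and nothing says whether the cultures were independent, so these p-values measure only the spread between these samples, which may be technical.

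By camera, 10 of the 42 lists were higher and 1 was lower in LoVo, though none passed with an estimated correlation (adjusted p = 0.903 with an estimated correlation for each). The latter version rests on 1 residual degree of freedom and could hardly call any list. Goblet and mucin genes had 10 of 17 higher in LoVo and 0 higher in HCT-15, among them AGR2, a folding factor for mucins (log2 5.16), and TFF1 (0.81). Among genes of ERK pathway output 10 of 18 were higher in LoVo and 1 in HCT-15, with DUSP5 at 2.45, DUSP6 at 2.39 and the ephrin receptor gene EPHA2 at 1.43. The NOTCH list had 10 of 13 higher and 3 lower, with the target HES1 at 3.44, HES2 at 4.64 and the modulator LFNG at 1.48. Cell migration and invasion genes had 15 of 27 higher and 4 lower, including S100A4 (3.96) and the integrin gene ITGB4 (2.51). Targets of p53 had 14 of 25 higher and 2 lower, with GDF15 at 2.09 and TP53I11 at 2.12. Angiogenic factors had 14 of 18 higher and 2 lower, with HBEGF at 1.29. Interferon response genes had 17 of 28 higher and 7 lower, with OAS1 at 4.27 and RIGI at -0.61, and enterocyte genes 8 of 16 higher and 4 lower, VIL1, the microvillus protein villin, being at -1.19. In the ribosomal protein list 18 of 52 were higher and 0 lower, and in oxidative phosphorylation 15 of 35 and 2. Genes of G1/S and DNA replication went the other way, with 2 of 30 higher and 19 lower, such as E2F1 at -0.35.

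For these 11 lists camera gave, at the preset correlation, the following values. The adjusted p was 2.42e-04 for angiogenic factors, 7.90e-04 for ribosomal proteins, 0.00462 for goblet and mucin genes, 0.00487 for G1/S and DNA replication and 0.00502 for p53 targets. It was 0.00704 for ERK output, 0.00705 for oxidative phosphorylation, 0.0126 for migration, 0.0224 for interferon response, 0.0231 for NOTCH and 0.0311 for enterocyte genes.

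**Figure D4:**
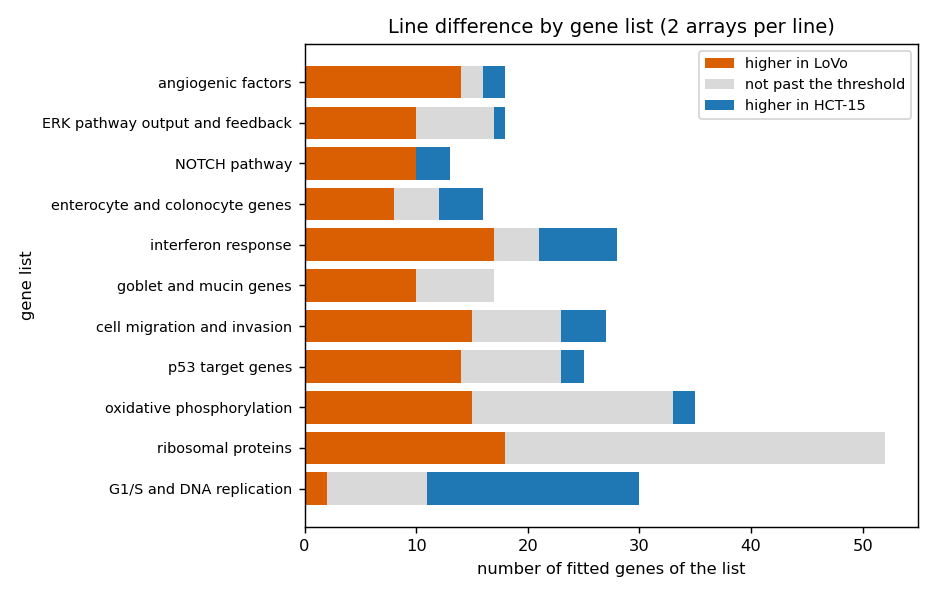
Number of genes (horizontal axis) of each list called for the line difference that were higher in LoVo, higher in HCT-15 or not past an adjusted p of 0.05, from 2 arrays per line. Goblet and mucin genes have 10 of 17 higher in LoVo and 0 higher in HCT-15, while G1/S and DNA replication has 2 of 30 and 19 of 30.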

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

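The tests of the trend with probe GC content and signal were set out before their results were seen, although the removal of that trend was an alternative chosen after seeing the data; the tests on other probes and on ERK output were chosen only after the result was seen.

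In 5 results the lines stood at opposite ends under anti-FGFR2IIIc. For a list, the medians lay at opposite ends of the matched random lists. For a gene with a symbol, the ratio was 2-fold or more higher in 1 line and lower in the other. Lists with medians on opposite sides of 0 but not at both ends were not counted. With 1 array per group none of the differences in these 5 results was tested. Single list members need not follow the median. Among immediate early genes, EGR1 (-0.47 in HCT-15 and -0.53 in LoVo) and FOS (-0.21 and -0.27) were below 0 in both lines. Limma called EGR1 lower with an intensity trend in the variance prior and with normexp background correction, but not with the main settings. KLF2 (-0.60 and 0.08) and FOSB (0.13 and -0.58) differed in sign. The list medians in LoVo minus HCT-15 differed by 0.31 on the log2 scale for TGF-beta and BMP target genes, by 0.17 for epithelial adhesion and junctions, by 0.14 for immediate early genes and by -0.25 for ribosomal proteins. The pseudogene transcript USP32P2 differed by -2.83, being 2-fold or more higher in HCT-15 and lower in LoVo.

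The NF-kB and inflammatory genes were higher in both lines. The tables argue against a trend of the ratio with GC content and signal as the cause, since the lower of the lines' list medians was 0.628 after the trend was removed and 0.630 before. Other measured probes of the members had a median log2 ratio of 0.765, but these 3 values of 3 genes (CXCL5, CXCL3 and PTGS2) are too few to decide on single noisy probes. For the list as a set, 16 of 18 genes in HCT-15 and 18 of 21 in LoVo lay above 0, each by its own probe. By 2-fold or more, 4 and 9 were higher and 0 lower, and both medians ranked at percentile 100 of matched random lists. These values argue against independent noise of single probes as the cause for the list, though not for any 1 gene. Lower FGF receptor signalling stays open as a biological cause, because the median antibody effect of the ERK output list, -0.00625, lies near 0 over members that go both ways and decides nothing. Any other difference between the antibody preparations may also be the cause, for every treated array had the one and every control array the other, so that antibody target and preparation cannot be told apart.

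In LoVo, cholesterol synthesis genes were lower and G2/M genes higher. After the trend with GC content and signal was removed, the LoVo cholesterol median was -0.283 (before, -0.293) with 1 of 24 genes above 0, and the G2/M median was 0.168 (before, 0.168) with 28 of 30 above 0, so the tables argue against that trend as the whole cause of either. A difference between the cultures other than the antibody, such as in density or feeding, was not tested and stays open with 1 array per group, as does an effect of the antibody.

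The lists at opposite ends in the lines differed in how they took the removal of the trend with GC content and signal, which differed between the lines: r of the ratio with probe GC percent was -0.188 in LoVo and 0.052 in HCT-15, and r with mean signal was 0.013 in LoVo and 0.137 in HCT-15. The ribosomal protein difference shrank from -0.247 to -0.0317, so that this trend is a candidate explanation for it. The differences stood at 0.348 for TGF-beta and BMP targets (percentiles 0.04 in HCT-15 and 99.99 in LoVo) and at 0.192 for immediate early genes (percentiles 0.25 and 99.2), which argues against the trend there. For epithelial adhesion the difference was 0.199 (before, 0.173) and did not shrink, and the HCT-15 percentile was 0. The LoVo percentile of 93.6, however, no longer lay at the end. By the criteria set beforehand the result for this list is therefore undecided. Removing the cause of the difference should have shrunk it, so the values argue against the trend as the cause of the difference between the lines. They do not settle the LoVo rank. A biological difference between the lines in their response is open and was not tested.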

How the results depend on the processing

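The removal of the loess trend on GC content and signal was an alternative chosen after seeing the data; the others were planned. In all, 78 counts and correlations stayed within 1.5 times or within their spread and 20 did not. For counts this compares sizes only and says nothing on direction. With normexp background correction, 33 genes in HCT-15 and 43 in LoVo reached 2-fold, 3 did so in both lines, limma called 149 genes for the antibody and camera 10 lists; that correction adds an offset, which shrinks ratios of dim genes, and the cause of the added calls was not tested. With genes above background on all 4 arrays, 4 genes and 8 lists were called, and an intensity trend in the prior gave 33 genes; the cause was not tested. Without the second term, camera called 3 lists; the cause was not tested. Without a filter on dim probes, 5186 genes differed between the lines; the cause was not tested. A threshold of 1.5-fold gave 370, 448 and 32 genes (HCT-15, LoVo, both) and 3-fold gave 43 in HCT-15 and 40 in LoVo, by construction, and a pseudocount 69 and 75. With an estimated correlation camera called 0 lists for the antibody and 0 for the lines, and fry called 0 for the antibody. The estimated correlation rests on 1 residual degree of freedom, so that version could hardly call any list. The NF-kB list was past the threshold in 9 of 11 settings (adjusted p from 3.21e-56 to 0.928), as were cholesterol (1.23e-07 to 0.928) and G2/M (5.24e-06 to 0.928), fatty acid synthesis in 6 (0.00529 to 0.928) and PI3K-AKT-FOXO in 7 (0.00602 to 0.928). Of single gene ratios, 2606 stayed within their error and 69 moved. A filter on genes leaves such ratios unchanged by construction. Of 240 line differences 0 moved, but these were of genes chosen for the largest differences, so that outcome was nearly fixed beforehand. Leaving out each array in turn, with a line term alone and the lone array assumed to vary like the other line, gave 8636 to 10077 line genes, against 11665 from all arrays with that term alone. With the trend removed, 103 and 111 genes reached 2-fold, 6 in both lines, and limma called 0 genes (1026 at an unadjusted p under 0.05) and camera 6 lists. Leaving out a line leaves no residual degree of freedom, and the deposited table allowed only the HCT-15 count, 104. Signal over background limits the small counts: 95.2% and 87.8% of the 2-fold genes were below the median signal.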

Other observations

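All values in this part were chosen after they were seen, and none was planned as a test. None of the genes of this paragraph passed the joint antibody test with the main settings. ZC3H12A, SDC4, CD83 and AGR2 were among the genes that limma called with an intensity trend in the variance prior and with normexp background correction. Outside the fixed list, ZC3H12A, which encodes a ribonuclease that degrades cytokine transcripts, had log2 ratios of 0.96 in HCT-15 and 1.03 in LoVo, the syndecan gene SDC4 of 0.73 and 1.13, and the immune surface gene CD83 of 0.55 and 0.67. AGR2, the mucin folding factor, had ratios of -0.62 and -0.76. Within the fixed list, other textbook targets of NF-kB stood near 0: SOD2 had ratios of 0.20 ± 0.20 and 0.12 ± 0.20, ICAM1 of 0.30 ± 0.20 and 0.00 ± 0.21, and LIF of -0.06 ± 0.20 and -0.14 ± 0.20.

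In the authors' deposited table the LoVo columns hold 64 values each, in its first 64 places, ordered by a control over treated ratio that falls from 5.09 to 2.005 (63 of 63 steps). Each pair matched exactly 1 spot on both LoVo arrays within 0.1% after scaling, and 0 matched the spot beside which it stood. All 64 matched spots were well above background and 2-fold or more lower with anti-FGFR2IIIc, and they are 64 of the 75 such probes found from the scanner files.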
